A study of Sus scrofa with 18 samples.

How the data were processed

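Liver RNA pools from piglets at postnatal day 21 were measured on Affymetrix porcine arrays, with 8 ug of RNA per sample per the labels. The samples form 6 groups of sex and diet (sow milk, milk formula, soy formula) with 3 pools each. The deposited values are an expression ratio per probe set and array, on a linear scale. Per the submitters' processing notes the tools were GCOS and RMA, and their versions are not given in the sources used here. The annotation build behind the probe sets is likewise not given in the sources used here. Tested on the table, 5271 of 24123 probe sets (21.9%) have a median of 1 over the 18 arrays within 0.002, and 0 have a median above 1. The deposited ratio is thus relative to the median of the probe set where that was high, and to something larger where it was low. The divisor is shared by all arrays, so it cancels in fold changes between arrays. The plan provided for RMA values on the log2 or the linear scale, and log2 was taken of the ratios once they were seen to be linear. All 18 columns of the table were matched to samples, with 0 left unmatched.

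Of the probe sets, 188 controls were set aside and 23935 were tested. By the array's annotation, 10069 of these name 1 gene (6765 distinct genes), 198 name several and 13668 name none. Symbols were matched against the gene reference, and 0 were updated. A gene was represented by its probe set with the highest mean log2 ratio. Genes not represented on the array, and any withheld, are not analysed here.

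A linear model with 1 mean per group was fitted in limma 3.58.1 (R 4.3.3) with empirical Bayes moderation (prior degrees of freedom 6.18). From it 14 contrasts were taken: 3 diet pairs over both sexes and within each sex, male against female over all diets and in sow-fed piglets, and 3 interactions of sex and diet. A diet contrast over both sexes is the mean of the within-sex differences. P-values were adjusted by the Benjamini-Hochberg method per contrast, with a threshold of 0.05. Gene lists (30 pathway lists and 11 cell marker lists, with 515 of 762 symbols measured) were written before the data were examined, as were the contrasts, the alternatives and the rule for naming genes. Lists with at least 5 measured genes (39) were tested with camera in limma, with a preset correlation of 0.01 and 1 probe set per gene. Counts adjusted over the list alone apply the same adjustment to the members of one list.

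The genes named are, per diet contrast over both sexes, the 10 largest rises and 10 largest falls past the threshold with one sign in both sexes and an official symbol. They also include up to 4 called members of each list that shifted or held at least 3 called genes, and 15 genes fixed in advance (some of which are not analysed here). Of the fixed genes, FTH1, CYP8B1, CPT1A and CYP2E1 were measured but passed the threshold in no diet contrast over both sexes. For male against female the genes named are the 5 largest rises and falls and the sex-linked list, and for interactions up to 5 called genes. Of the genes named outside that rule, members of marker lists were chosen after their values were seen, and ID2 and ID3 before.

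Each count and each named gene was recomputed with trended and robust variances, quantile normalization, the pool number as a replicate block, and each array left out in turn. Counts were also recomputed with median centring of arrays, without the dimmest 40% of probe sets, with array weights, with only the groups compared, with 1 probe set per gene, with adjustment over all contrasts, and with a 1.5-fold limit, with and without adjustment. Named genes and lists were also tried with the mean of all probe sets of a gene, and lists with an estimated correlation. Array weights by sex, and fits to the arrays of one sex, were added after seeing the data. Principal components, tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

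The model was tested on simulated data with the measured spread of each sex. It recovered 85.6% of 2-fold changes on soy formula over both sexes, with 9.70% false among the calls. Within males it gave 58.4% false calls and a fit to male arrays alone 4.61%, though that recovered 13.6% of 2-fold changes. Within females a fit to female arrays alone recovered 90.0% with 5.08% false. In 20 simulations camera recovered the shifted list 20 times and called 2 unshifted lists. The simulated genes were drawn independently of each other, so this could not test camera on lists whose genes correlate. Pool numbers do not pair samples: the median residual correlation of arrays with the same number and sex was -0.008, so no paired result is given except as an alternative. Left out were probe sets without a gene name in the list tests, and absolute levels, which the ratios do not hold. The number of arrays limits the precision of every value.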

Results

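Liver RNA from piglets aged 21 days was hybridised to porcine expression arrays. The piglets were suckled by the sow, or were fed a formula based on cow's milk or on soy from day 2. Each of the 6 groups (3 diets, 2 sexes) held 3 RNA pools, which gave 18 arrays, 9 per sex and 6 per diet. The number of animals per pool is not stated in the sources used here, so p-values measure the spread between pools, and the number of arrays limits the precision. Each value was an expression ratio of 1 probe set on 1 array, and the array medians ran from 0.301 to 0.309. The ratios were used to compare arrays for one gene, and not one gene with another. A gene is said to have risen or fallen only where it passed the adjusted p threshold of 0.05, and changes are log2 differences averaged over both sexes unless a sex is named.

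The first principal component held 60.3% of the variance and separated the 9 male from the 9 female arrays. The second held 6.45% and followed the diet in both sexes. Its scores ran from 16.4 to 27.4 on sow milk, from -7.27 to 4.64 on milk formula and from -23.1 to -15.3 on soy formula. Across probe sets, which are not independent replicates, the median correlation was 0.918 between arrays of one group, 0.901 between diets of one sex and 0.771 between the sexes. Control transcripts added during array processing were 7.17-fold higher on male arrays. An array batch that goes with sex may be behind this, though the labels name no batch. Diets were compared within each sex and the 2 differences averaged, as planned before the data were examined.

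**Figure D1:**
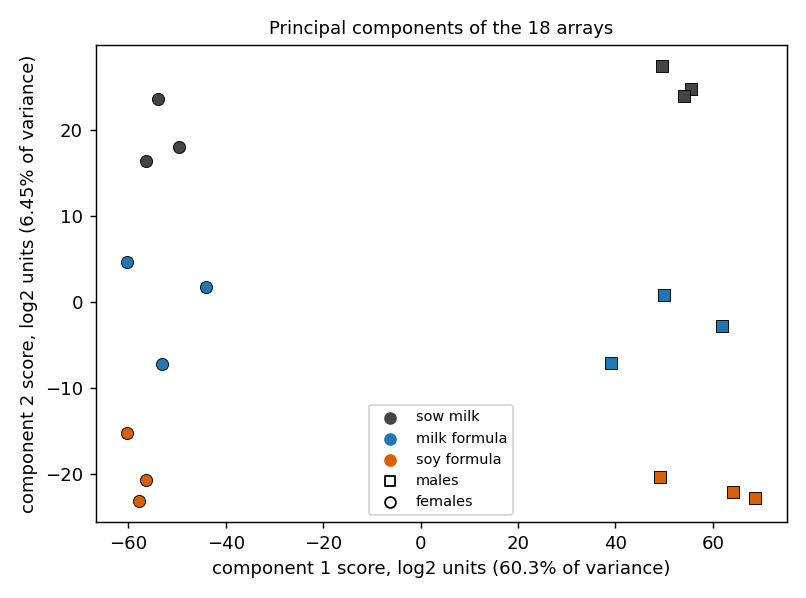
Scores of the 18 arrays on the first 2 principal components of the log2 ratios, with diet as colour and sex as marker shape. The first component (60.3% of the variance) splits the sexes, and the second (6.45%) runs from sow milk at the top to soy formula at the bottom in both sexes.

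The comparison of milk formula with sow milk asks how a formula based on cow's milk changes gene expression in the neonatal liver. HAMP, which encodes the iron hormone hepcidin, rose 31.1-fold (log2 4.96, SE 0.22, adjusted p = 1.87e-10, 6 arrays per diet), by 4.24 in males and 5.68 in females. TFRC, the transferrin receptor through which cells take up iron, fell by 2.47 (SE 0.21), and ID1, a target of the BMP pathway, rose by 2.31 (SE 0.17). Cholesterol synthesis rose along the pathway: HMGCS1, its first committed step, by 3.75 (SE 0.30), FDPS by 2.86 (SE 0.14), SQLE by 2.77 (SE 0.20) and CYP51 by 2.81 (SE 0.16). AFP fell by 2.11 (SE 0.45), the 1 called of 6 fetal liver genes, with 0 higher and 5 not called (list adjusted p = 0.0271, and adjusted p = 0.195 with an estimated correlation). PEG10 fell by 2.11 (SE 0.38). AFP was lower on 5 of 6 formula arrays, whereas the other named genes past the threshold here moved one way on 6 of 6. Each formula array was set against the mean of the sow-fed arrays of its sex. The genes were called on these same arrays, a choice that raises such counts. The fall of AFP had adjusted p = 0.032 here and up to 0.352 over the alternatives, in 11 of which it was not past the threshold.

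By list, 10 of 13 measured cholesterol synthesis genes rose on milk formula, 0 fell and 3 were not called, and 12 rose when adjusted over the list alone. Their median was 1.73, and the camera test gave adjusted p = 1.11e-37, or adjusted p = 0.0007 with an estimated correlation. Of 17 lipogenesis genes 4 rose, 0 fell and 13 were not called (11 rose adjusted over the list alone, median 0.53, adjusted p = 1.21e-12, and adjusted p = 0.0298 with an estimated correlation). The 4 were the desaturases SCD (2.65, SE 0.20) and FADS1 (1.68, SE 0.18), the acetate-activating enzyme ACSS2 (1.32, SE 0.20) and PNPLA3 (1.12, SE 0.20), the last of which had adjusted p up to 0.0888 over the alternatives. FASN, at 0.74 (SE 0.22), missed the threshold (adjusted p = 0.182). Of 10 gluconeogenesis genes 0 were called, but 5 fell adjusted over the list alone, and the list shifted down (median -0.34, adjusted p = 3.7e-04, and adjusted p = 0.0492 with an estimated correlation). Its best-known member, PCK1, stood at -1.48 (SE 0.39, adjusted p = 0.102).

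A minority of urea cycle, complement and acute-phase genes was called lower on milk formula, and these 3 lists lost their call with an estimated correlation. CPS1, the entry enzyme of the urea cycle, fell by 1.11 (SE 0.14) and OAT by 1.21 (SE 0.18). They were the 2 called of 18 urea cycle and amino acid breakdown genes, of which 8 fell adjusted over the list alone (median -0.27, adjusted p = 2.12e-06, and adjusted p = 0.195 with an estimated correlation). Of 22 complement and coagulation genes, C5 (-0.74, SE 0.15) and C4A (-0.54, SE 0.12) fell, 0 rose and 20 were not called (6 fell adjusted over the list alone, median -0.20, adjusted p = 1.06e-07, and adjusted p = 0.386 with an estimated correlation). Both lost their call in some fits without 1 array and with array weights by sex (adjusted p up to 0.162 for C5 and 0.185 for C4A), C5 also after quantile normalization and C4A with trended variances. Among 15 acute-phase genes LBP (-0.96, SE 0.18), ITIH4 (-0.86, SE 0.14) and ORM1 (-0.70, SE 0.11) fell, while CRP rose by 1.88 (SE 0.27) and 11 were not called. With array weights by sex LBP (adjusted p = 0.172), ITIH4 (0.0991) and CRP (0.0665) lost their call, as did ORM1 with the mean of all its probe sets (0.359). The acute-phase list shifted down (median -0.17, adjusted p = 5.74e-04, and adjusted p = 0.398 with an estimated correlation), with 1 higher and 4 lower adjusted over the list alone. Of 12 hepatocyte markers 1 rose, 1 fell and 10 were not called (1 higher and 3 lower adjusted over the list alone, median -0.12, adjusted p = 0.0126, and adjusted p = 0.398 with an estimated correlation).

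Across the array 181 of 23935 probe sets were called, 109 higher and 72 lower, and among 6765 named genes 60 were higher and 41 lower. The direction was shared by both sexes for 99.4% of the 181, a share raised by calling on the mean of both. Of 177 probe sets called in females fitted alone, 87% had the same sign in males. Leaving out 1 array gave 97 to 217 called probe sets, with 97 without female milk formula replicate 3, 106 without female sow-fed replicate 3, 113 without female sow-fed replicate 2 and 114 without female sow-fed replicate 1.

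The comparison of soy formula with sow milk asks the same of a soy-based formula. HMGCS1 rose 35.6-fold (log2 5.15, SE 0.30, adjusted p = 3.38e-09, 6 arrays per diet), by 4.39 in males and 5.92 in females. HAMP rose by 4.65 (SE 0.22), TFRC fell by 2.54 (SE 0.21) and ID1 rose by 1.99 (SE 0.17). CYP7A1, the first and rate-setting enzyme of bile acid synthesis, rose by 4.22 (SE 0.42, adjusted p = 4.45e-06), with 2.62 in males and 5.82 in females. On the sow-fed arrays its ratio was 0.170 to 0.312, the level of dim probe sets, so the size of this rise is not exact. PCK1, the entry enzyme of gluconeogenesis, fell by 2.96 (SE 0.39), and the ferritin light chain FTL fell by 1.18 (SE 0.16). Of the 71 rule-named genes past the threshold, 69 moved one way on 6 of 6 soy arrays, and ACADL and NQO1 did so on 5 of 6. Here too the genes were called on these same arrays, which raises such counts.

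Of 13 cholesterol synthesis genes 12 rose on soy formula, 0 fell and 1 was not called (12 also adjusted over the list alone), with a median of 2.16 and adjusted p = 7.26e-36, or adjusted p = 8.93e-04 with an estimated correlation. FDPS rose by 3.52 (SE 0.14), SQLE by 3.30 (SE 0.20) and CYP51 by 3.24 (SE 0.16). Of 17 lipogenesis genes 10 rose, 0 fell and 7 were not called (12 rose adjusted over the list alone, median 0.52, adjusted p = 3.27e-16, and adjusted p = 0.0115 with an estimated correlation). SCD rose by 3.50 (SE 0.20), ACSS2 by 2.45 (SE 0.20), FADS1 by 2.32 (SE 0.18) and FASN, the fatty acid synthase, by 1.68 (SE 0.22). Of 8 bile acid genes CYP7A1 and the transporters SLC10A1 (0.59, SE 0.12) and ABCB11 (0.56, SE 0.15) rose, 0 fell and 5 were not called, with 3 higher adjusted over the list alone. ABCB11 had adjusted p = 0.038, up to 0.154 over the alternatives, in 13 of which it was not past the threshold. That list lost its call (adjusted p = 0.00876, and adjusted p = 0.23 with an estimated correlation).

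Of 25 drug-metabolising enzymes and receptors 7 rose on soy formula, 1 fell and 17 were not called (9 higher and 1 lower adjusted over the list alone), and the list lost its call with an estimated correlation. CYP3A29 rose by 2.80 (SE 0.22), CYP1A1 by 1.68 (SE 0.23), CYP3A46 by 1.65 (SE 0.20) and CYP2D25 by 1.64 (SE 0.12). The chaperones HSP70.2 (1.96, SE 0.32), HSPA8 (1.14, SE 0.19) and HSPD1 (0.61, SE 0.13) rose among 9 heat shock genes, of which 6 were not called and 6 rose adjusted over the list alone. Over the alternatives the adjusted p reached 0.0878 for HSPA8 and 0.0926 for HSPD1, each past the threshold in all but 1. The drug enzyme list had a median of 0.28 (adjusted p = 1.29e-04, and adjusted p = 0.23 with an estimated correlation). The heat shock list had a median of 0.53 (adjusted p = 9.23e-05, and adjusted p = 0.264 with an estimated correlation). On milk formula against sow milk CYP3A29, CYP2D25, HSP70.2 and HSPA8 were called higher too (limma adjusted p = 3.72e-04, 0.022, 0.043 and 0.043), and SULT2A1 lower (0.0104). There CYP2D25 was not past the threshold in 7 alternatives, HSP70.2 in 15 and HSPA8 in 16. Both lists passed the camera test on milk formula too, and lost their call with an estimated correlation.

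Lists with lower genes on soy formula included complement, acute-phase and macrophage genes, of which the first 2 lost their call with an estimated correlation. Of 22 complement and coagulation genes 11 fell, 0 rose and 11 were not called (17 fell adjusted over the list alone), among them C5 (-1.46, SE 0.15), CFB (-0.75, SE 0.12) and C9 (-0.70, SE 0.11). C9 lost its call with the mean of all its probe sets (adjusted p = 0.352). The list median was -0.58 (adjusted p = 3.27e-16, and adjusted p = 0.121 with an estimated correlation). Of 15 acute-phase genes 8 fell, 1 rose and 6 were not called (10 lower and 1 higher adjusted over the list alone, median -0.39, adjusted p = 6.4e-07, and adjusted p = 0.191 with an estimated correlation). ITIH4 fell by 1.92 (SE 0.14) and ORM1 by 0.93 (SE 0.11), and CRP rose by 1.54 (SE 0.27), with adjusted p up to 0.0681 over the alternatives. Of 9 macrophage markers 6 fell, 0 rose and 3 were not called (6 fell adjusted over the list alone), with VSIG4 at -1.0 (SE 0.16), CD5L at -0.92 (SE 0.16) and C1QA at -0.72 (SE 0.14). Their median was -0.72 (-0.54 in males and -0.78 in females), with adjusted p = 2.56e-07 and adjusted p = 0.0248 with an estimated correlation. Of 9 endothelial markers 2 fell, 0 rose and 7 were not called (5 fell adjusted over the list alone, median -0.47, adjusted p = 9.85e-06, and adjusted p = 0.0937 with an estimated correlation).

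Across the array 784 of 23935 probe sets were called, 365 higher and 419 lower, and among 6765 named genes 181 were higher and 199 lower. Both sexes shared the direction for 98.1% of the 784, and of 1595 called in females fitted alone 75.6% had the same sign in males. Among females 28S ribosomal RNA averaged 0.105 on soy formula and 0.202 on sow milk, while among males it averaged 3.76 and 3.05. Male soy formula replicate 2 had the lowest array weight (0.314). Leaving out 1 array gave 495 to 896 called probe sets, with 495 and 512 without female soy formula replicates 2 and 3, and 514, 514 and 498 without female sow-fed replicates 1, 2 and 3.

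**Figure D2:**
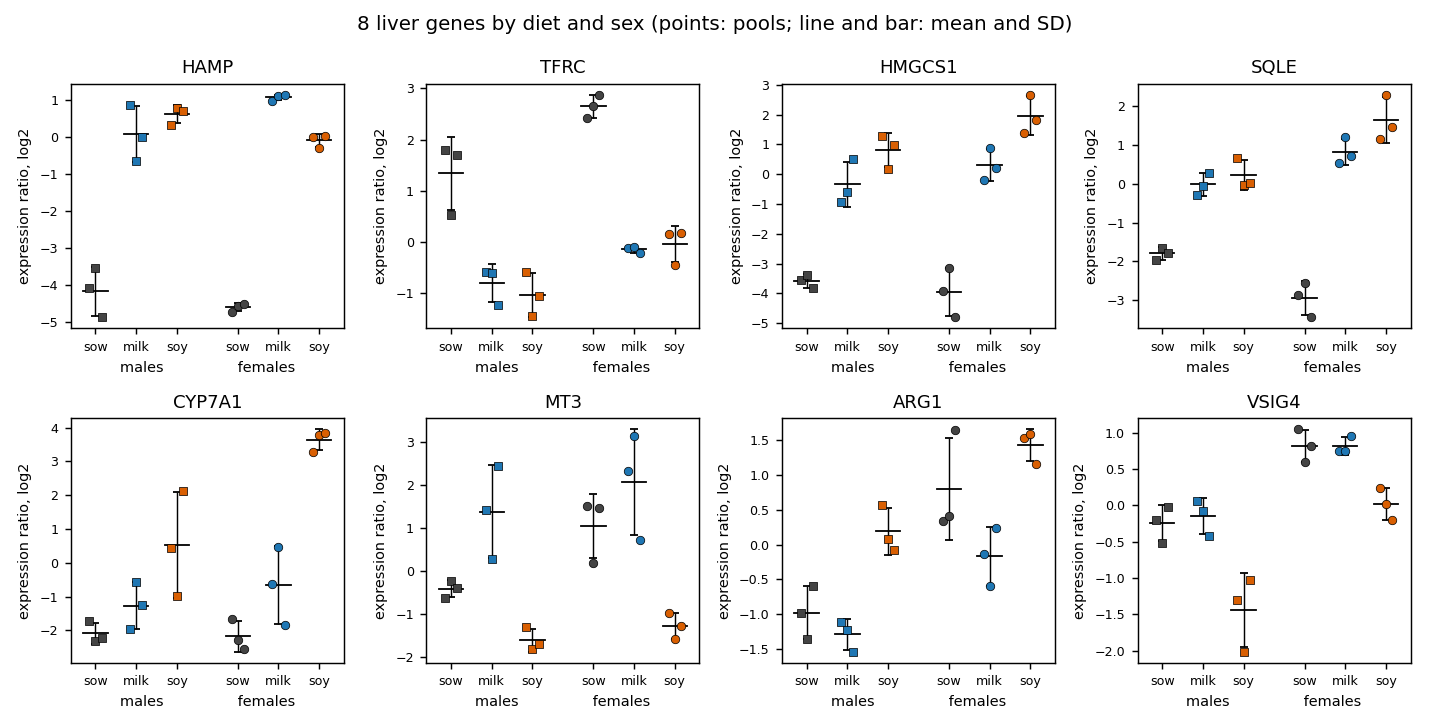
Expression ratio (log2) of 8 genes on each array, by diet and sex, with points for the 3 pools of a group, a line for their mean and a bar for 1 SD. HAMP was higher and TFRC lower on both formulas (log2 4.96 and -2.47 on milk formula against sow milk), whereas CYP7A1 rose (3.05) and MT3 fell (-3.17) on soy against milk formula.

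The responses to both formulas overlapped. Of 109 probe sets higher on milk formula 77 were also higher on soy formula, where independent responses would share 1.66, and of 72 lower 55 were shared (1.26 if independent). Of the 832 probe sets called in either comparison, 763 (91.7%) had the same sign in both, a share raised by that selection. Over all probe sets it was 68.1%, against 66.7% simulated with no shared effect, and 54.4% with the sow-fed arrays divided. HAMP, ID1, FDPS and SCD are examples of shared rises, and TFRC, PEG10 and CXCL14 of shared falls. Both comparisons use the same sow-fed arrays, which alone would make the changes correlate by 0.50 across probe sets against 0.65 measured. With the sow-fed arrays divided between the comparisons in 18 ways, 34 to 57 probe sets were shared (median 49), and the correlation across probe sets was 0.318 to 0.372.

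The comparison of soy formula with milk formula asks which effects differ between the 2 formulas, whose composition is not given. CYP7A1 was higher on soy formula by 3.05 (SE 0.42, adjusted p = 0.00122, 6 arrays per diet), a size not exact where milk formula arrays were dim, and by 1.80 in males and 4.31 in females. Among metallothioneins, which bind zinc and copper, MT3 fell by 3.17 (SE 0.36), MT1A by 1.80 (SE 0.19) and MT-2B by 1.18 (SE 0.19). The family was not tested as a list. FTL fell by 1.18 (SE 0.16), and HAMP was not called (-0.31, SE 0.22, adjusted p = 0.69). The urea cycle genes ARG1 (1.54, SE 0.22), ASL (0.95, SE 0.14) and CPS1 (0.92, SE 0.14) were higher. The named genes past the threshold in this comparison moved one way on 6 of 6 soy arrays, each set against the milk formula mean of its sex. These genes were called on the same arrays, which raises such counts. Single pools of the 2 diets still overlapped for some genes. In males CYP7A1 was 0.502 on soy formula replicate 2 and 0.667 on milk formula replicate 2.

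Of 18 urea cycle and amino acid breakdown genes 5 rose on soy against milk formula, 0 fell and 13 were not called (6 rose adjusted over the list alone, median 0.14, adjusted p = 9.76e-06, and adjusted p = 0.232 with an estimated correlation). Of 9 macrophage markers 5 fell, 0 rose and 4 were not called (6 fell adjusted over the list alone), C1QC by 0.83 (SE 0.11) and VSIG4 by 1.05 (SE 0.16) among them. Their median was -0.82 (adjusted p = 9.01e-10, and adjusted p = 0.0207 with an estimated correlation). Of 9 endothelial markers 0 were called, with 4 lower adjusted over the list alone (median -0.29, adjusted p = 0.00253, and adjusted p = 0.232 with an estimated correlation). Of 15 antigen presentation genes 4 fell, 0 rose and 11 were not called (10 lower and 1 higher adjusted over the list alone, median -0.51, adjusted p = 2.22e-07, and adjusted p = 0.13 with an estimated correlation). The lysosomal protease CTSS (-1.25, SE 0.17) and the class II gene SLA-DRA (-1.23, SE 0.21, adjusted p up to 0.141 over the alternatives) were among the 4. DEFB1, a defensin, fell by 1.78 (SE 0.24) and the adhesion molecule ICAM1 by 1.07 (SE 0.18).

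Of 13 cholesterol synthesis genes 3 were higher on soy than on milk formula, 0 lower and 10 not called (10 higher adjusted over the list alone, median 0.53, adjusted p = 3.42e-10, and adjusted p = 0.0787 with an estimated correlation). HMGCS1 stood at 1.40 (SE 0.30, adjusted p = 0.0355) and TM7SF2 at 0.88 (SE 0.16), and SQLE was not called (0.53, SE 0.20). HMGCS1 was not past the threshold in 10 alternatives (adjusted p up to 0.223) and TM7SF2 in 1 (0.0505). Of 22 complement and coagulation genes 4 fell, 0 rose and 18 were not called, with C4BPA at -0.68 (SE 0.11, adjusted p up to 0.0587 over the alternatives); 10 fell adjusted over the list alone (median -0.28, adjusted p = 4.43e-07, and adjusted p = 0.273 with an estimated correlation). The drug enzymes CYP2D25 (1.02, SE 0.12), CYP3A29 (1.12, SE 0.22) and CYP3A46 (0.99, SE 0.20) rose, 3 of 25, with 0 lower and 22 not called (6 higher and 3 lower adjusted over the list alone, median 0.14, adjusted p = 0.0138, and adjusted p = 0.408 with an estimated correlation). CYP3A29 was not past the threshold in 5 alternatives (adjusted p up to 0.139) and CYP3A46 in 6 (0.2).

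In this comparison 158 probe sets were called, 62 higher and 96 lower, and among the named genes 30 were higher and 56 lower. Both sexes shared the direction for 98.7% of the 158, and of 539 called in females fitted alone 69.6% had the same sign in males. Without male soy formula replicate 1 the count was 260, and it was 82 and 73 without female soy formula replicates 2 and 3, and 79 and 82 without female milk formula replicates 1 and 2.

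**Figure D3:**
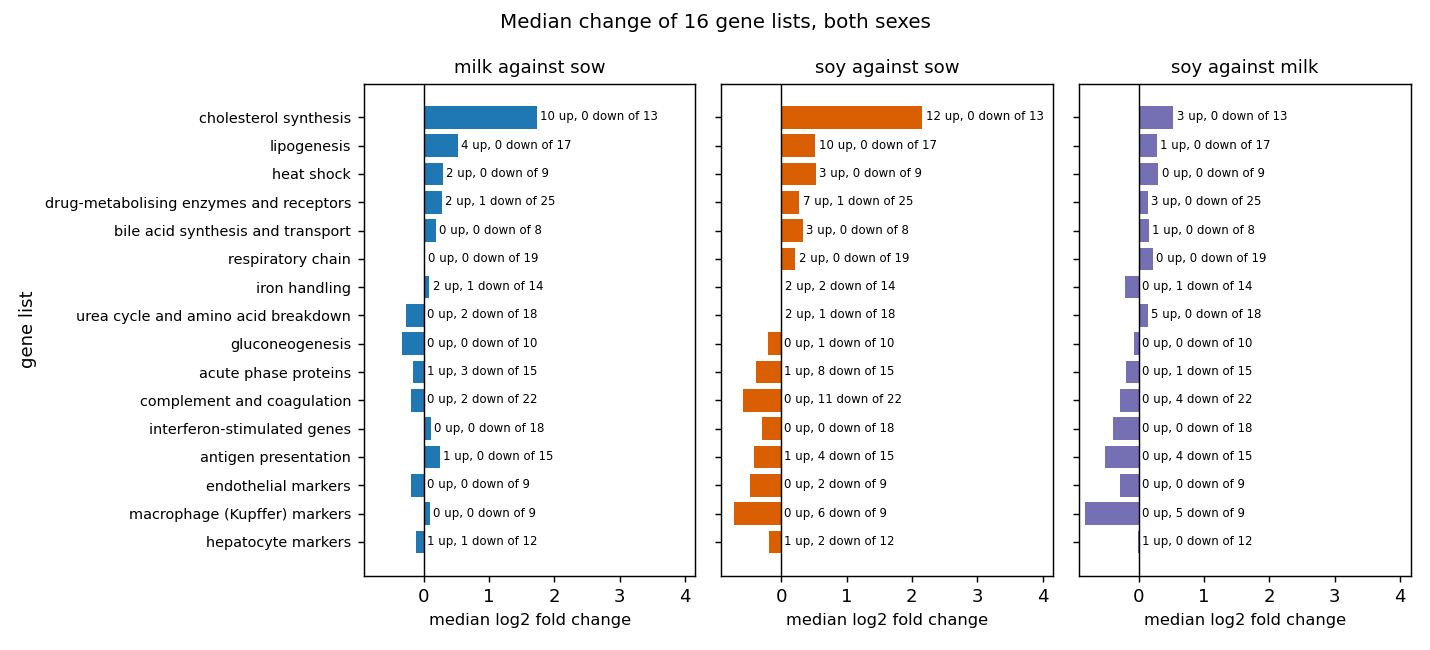
Median log2 fold change of 16 gene lists in the 3 diet comparisons over both sexes, with the genes called higher and lower beside each bar. Cholesterol synthesis had the highest median on milk formula (1.73) and on soy formula (2.16), and the macrophage markers the lowest on soy formula against sow milk (-0.72) and against milk formula (-0.82).

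Within each sex FDPS rose by 2.50 in males and 3.22 in females on milk formula, and by 3.13 and 3.91 on soy formula. TFRC fell by 2.14 in males and by 2.80 in females on milk formula. With the spread pooled over all arrays, 196 probe sets were called in males on milk formula against sow milk (121 higher, 75 lower), 484 on soy formula against sow milk (209 higher, 275 lower) and 167 on soy against milk formula (53 higher, 114 lower). In females the counts were 77 (48 higher, 29 lower), 330 (192 higher, 138 lower) and 58 (38 higher, 20 lower). Male arrays varied more within groups (median SD 0.324 in log2 units against 0.134 in females), and in simulated data the pooled spread gave 58.4% false calls in males and 1.92% in females. Fitted alone, males gave 23, 68 and 0 calls and females 177, 1595 and 539 in the same order, after the fit was chosen with the data in view. The majority turned for the 177 (81 higher, 96 lower) and for the 68 in males on soy formula (40 higher, 28 lower), and the 23 were 19 higher and 4 lower. In those separate fits 17 probe sets were higher and 2 lower in both sexes on milk formula, and 39 and 17 on soy formula, with 0 of opposite sign.

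Males and females differed at 14977 of 23935 probe sets (62.6%), 6170 higher and 8807 lower in males, and at 8626 (2062 higher, 6564 lower) among sow-fed piglets alone. Signs of RNA and array quality moved with sex too: 28S ribosomal RNA was 21.2-fold higher on male arrays, and the relative 3' to 5' ratio of GAPDH averaged 0.658 (0.590 to 0.720) in males and 1.11 (0.963 to 1.25) in females. The chosen probe set of the growth factor IGF2 was higher in males by 1.94 (SE 0.23, 9 arrays per sex), but called probe sets of this gene went both ways and the mean of all its probe sets was not called (0.29, adjusted p = 0.0845). Such called probe sets of both signs were found for 352 genes in this comparison. RIN3 was higher by 1.28 (SE 0.09) and ID4 by 1.35 (SE 0.13). NDFIP2 was lower by 2.66 (SE 0.11), RCN2 by 2.60 (SE 0.15) and INSIG2, a brake on sterol synthesis, by 2.51 (SE 0.14), written as male minus female values of -2.66, -2.60 and -2.51. Of 7 sex-linked genes the Y-linked EIF1AY (0.83, SE 0.17) and SRY (0.37, SE 0.09) were higher in males. On female arrays EIF1AY ran from 0.115 to 0.145 and SRY from 0.148 to 0.177, the level of dim probe sets. SRY on male arrays (0.173 to 0.258) overlapped with females. Probe sets with a median under 0.25 were 0.21 higher in males as a class, so these 2 sizes are not exact. The X-linked EIF1AX (-1.56, SE 0.12), KDM6A (-0.68, SE 0.14) and USP9X (-0.65, SE 0.12) were lower, and KDM5C (-0.07) and ZFX (-0.05) were not called. USP9X turned to 0.04 (adjusted p = 0.842) after quantile normalization. The 19 respiratory chain genes were all lower in males (median -0.94, adjusted p = 0.00425, and adjusted p = 0.505 with an estimated correlation), and 19 were lower adjusted over the list alone. That list lost its call after quantile normalization too, and the 5223 tested probe sets with a median ratio of 1 had a median of -0.94 as well, so no shift particular to the list is shown. The labels name no batch, and in this comparison sex and an array batch that follows it cannot be told apart.

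The difference between the sexes in diet response was tested as an interaction. On milk formula against sow milk 1 probe set was called, for APCS, serum amyloid P, which rose by 2.69 in females and was not called in males (0.35, adjusted p = 0.542; difference -2.34, SE 0.32, adjusted p = 0.0234). On soy formula against sow milk 3 were called, with SQLE at 2.02 in males and 4.59 in females (difference -2.57, SE 0.40, adjusted p = 0.0386). On soy against milk formula limma called 0 probe sets, with 1772 at an unadjusted p under 0.05. There limma with quantile normalization called 2, and limma with adjustment over all comparisons together called 198. That adjustment pools in male against female, where 62.6% of probe sets were called, which loosens the threshold here. The 198 thus do not show an interaction.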

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

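The splits of arrays and the test on ID2 and ID3 were chosen before their results were seen, and the other tests in this part only after the result was seen. The interaction calls below were picked out because the diet effect differed between males and females.

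On milk formula against sow milk the male change of APCS minus the female change was -2.34 (SE 0.32, adjusted p = 0.0234), with 0.35 in males and 2.69 in females. On soy formula against sow milk SQLE differed by -2.57 (SE 0.40, adjusted p = 0.0386), with 2.02 in males and 4.59 in females. A probe set of PRELID3B differed by -1.63 (SE 0.22, adjusted p = 0.012), and a probe set that names no gene by -2.16 (SE 0.32, adjusted p = 0.0304). Over the alternatives the adjusted p of APCS ran from 0.00422 to 0.196 and that of SQLE from 0.0242 to 0.327. APCS was not past the threshold in 11 alternatives and SQLE in 15. Both were past it with trended variances, but not after quantile normalization, with array weights by sex or in some fits without 1 array. SQLE was also not past it with the replicate block. All 4 of these changes were lower in males than in females. With adjustment over all comparisons 58.6% of the calls on milk formula and 40.9% on soy formula against sow milk went the other way. The splits of arrays could not decide on chance for these counts, and chance is not excluded. They exchange male and female arrays, which mixes the sex difference, or a batch that follows it, into the contrast. On milk formula the real split called 1 probe set and the highest of the others 5427, with 9 of 100 splits calling as many. On soy formula against sow milk the real split called 3 and the highest other 5493 (15 of 100 splits). On soy against milk formula they called 0 and 7124 (100 of 100), an outcome fixed in advance, as any split reaches 0.

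For the diet effects over both sexes chance can be excluded as the whole source of the counts. With 1 of 100 splits as large, the real one, the counts were 181 on milk formula against sow milk (highest other 29), 784 on soy formula against sow milk (highest other 185) and 158 on soy against milk formula (highest other 54). Within one sex 10 splits are too few for such a test. In males the real counts were 196, 484 and 167 and the highest others 43, 82 and 135, and in females 77, 330 and 58 with highest others of 0, 0 and 0. For male against female over all diets chance can be excluded (14977, highest other 9773, 1 of 100 splits), and that other count points to the structure by sex that a split shares in part. Among sow-fed piglets the 10 splits are too few (8626, highest other 1).

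The first pattern is the difference between male and female arrays at 62.6% of probe sets. The sex of the animals as the whole cause is argued against by control transcripts that are not liver RNA: the lowest male array was 3.18 times the highest female array for them. An array batch that follows the sexes may account for part of the pattern, since these controls were 7.17-fold higher on the 9 male arrays. The bright probe sets with a median ratio of 1 were shifted by -0.94 in males (5223 probe sets) and those with a median under 0.25 by 0.21, so the difference depends on the signal level. For any single gene, IGF2 and the X-linked EIF1AX included, sex and an array batch that follows it cannot be told apart, since they would coincide.

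The second pattern is the fall of macrophage markers on soy formula against sow milk. An array batch that follows the sexes cancels in diet differences taken within each sex. The medians of -0.78 in females and -0.54 in males thus could not test it. Lower signal of all bright probe sets on the soy arrays is argued against by their median of -0.0197 (5223 probe sets), above the upper quartile of the markers (-0.41). A higher share of hepatocyte RNA diluting every other cell type is argued against by 14 endothelial, stellate and bile duct markers that are not dim (median ratio above 0.5), whose mean was 0.36 (SE 0.14) above that of 8 macrophage markers. This gap came from the 8 stellate and bile duct markers, on which alone the test was first made (0.56, SE 0.16), as the 6 endothelial markers, of which 2 were called, had a median of -0.55 (gap 0.10, SE 0.12). A cause shared by endothelial cells and macrophages thus stays open. The SEs of these gaps are taken over marker genes, which share the same arrays and are not independent replicates. Some of the 14 markers lay near the limit for dim ones (SPP1 at 0.501, DES at 0.54, EPCAM at 0.601), whereas the 8 macrophage markers had a median ratio of 1. The gap thus argues only weakly against dilution. A lower share of macrophages as the whole cause could not be decided. The falls were unequal: Cochran's Q over its degrees of freedom was 3.12 (95% bound 2.01), with CD14 at -0.23 (SE 0.13) and VSIG4 at -1.0 (SE 0.16). Fewer macrophages would give equal falls only if macrophages alone made each marker and all probe sets responded alike, which was not tested. Fewer macrophages alone thus stay open as a cause. Fewer macrophages together with lower expression in those that remain also stay open, as does a direct effect of diet on these genes, both untested.

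The third pattern is the rise of HAMP on both formulas. An array batch that follows the sexes cancels within one sex, so fits to one sex alone could not test it. In those fits HAMP was past the threshold and higher in 4 of 4, with adjusted p from 9.79e-10 to 7.79e-04. Inflammatory signalling, a known inducer of hepcidin, could not be decided: the acute-phase list did not pass the test with an estimated correlation (adjusted p = 0.398 on milk formula and 0.191 on soy formula), and CRP was higher on both. An earlier count of acute-phase genes below 0 (12 of 15 on each formula) had its bound set after the data were seen, at 12, and decides nothing. BMP signalling through the ID genes, which iron loading triggers, could not be decided: ID1 rose by 2.31 and 1.99, but ID2 and ID3 averaged 0.0673 over both formulas, with ID3 at 0.46 (SE 0.14) on milk formula and -0.26 (SE 0.14) on soy formula. A higher iron intake from formula than from sow milk may underlie the rise of HAMP and the fall of TFRC. This is a hypothesis from the same data and from 1 HAMP probe set, with the iron content of the diets not given. The ferritin genes did not rise with HAMP on soy formula, where FTL fell (limma adjusted p = 2.59e-04) and FTH1 was not called (0.568). On milk formula FTH1 was not called either (limma adjusted p = 0.876). Iron measured in the diets and in the same livers would decide this hypothesis.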

How the results depend on the processing

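Array weights by sex and fits to the arrays of one sex were chosen only after the result was seen, and the other alternatives before the data were examined. Counts named in order are milk formula against sow milk, soy formula against sow milk, and soy against milk formula, and for each alternative the counts given are those that moved by over 1.5 times. The cause was not tested except where the alternative itself sets it, as with fewer probe sets or arrays tested. Adjustment over all comparisons pools in male against female with its many calls, which loosens the threshold for the diet comparisons and interactions.

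Of the named genes past the threshold, quantile normalization kept 33 of 37 on milk formula against sow milk, 66 of 71 on soy formula against sow milk and 34 of 38 on soy against milk formula. The mean of all probe sets of a gene kept 32, 64 and 37, trended and robust variances 36, 68 and 36, and array weights by sex 22, 53 and 20. Across all 18 fits that leave out 1 array 26, 55 and 25 remained, and none of the named genes of the diet comparisons reversed in any alternative tried for them. One gene of the comparison of sexes did, USP9X, which turned from -0.65 to 0.0352 after quantile normalization (adjusted p = 0.842). Pool numbers do not pair the samples; with the number as a replicate block 36, 68 and 37 named genes were kept, and the blocked counts over both sexes were 158, 798 and 156.

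Over both sexes array weights gave 87, 498 and 62 called probe sets, and array weights by sex 77, 516 and 70. Adjustment over all comparisons together gave 486 on milk formula against sow milk and 556 on soy against milk formula, and unadjusted p with a 1.5-fold limit 397 and 443. With 1 probe set per gene soy formula against sow milk gave 476. Leaving out 1 array gave 97 to 217, 495 to 896 and 73 to 260, and the arrays behind the larger moves are named with the comparisons. Dividing the sow-fed arrays between both formula comparisons lowered the shared calls from 132 to 49.

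In males array weights gave 3, 31 and 0, array weights by sex 3, 29 and 0, only the groups compared 22, 54 and 0, and only male arrays 23, 68 and 0. One probe set per gene gave 99, 232 and 63, adjustment over all comparisons 659, 874 and 677, and unadjusted p with a 1.5-fold limit 1435, 1821 and 1471. Without dim probe sets soy against milk formula gave 99. Without 1 array the counts ran over 117 to 315, 354 to 761 and 45 to 499. On milk formula against sow milk male soy formula replicates 2 and 3 gave 315 and 295 when left out, female sow-fed replicates 1, 2 and 3 gave 117, 119 and 118, female milk formula replicate 2 gave 120, and female soy formula replicates 1, 2 and 3 gave 117, 129 and 123. Without male soy formula replicate 1 the count was 761 on soy formula against sow milk and 499 on soy against milk formula. The latter was 45, 53 and 63 without female sow-fed replicates 1, 2 and 3, 56, 87 and 65 without the female milk formula replicates, and 54, 51 and 51 without the female soy formula replicates. With only male arrays the share of calls that are higher rose to 82.6% on milk formula and 58.8% on soy formula against sow milk, from 61.7% and 43.2%. The latter was 66.7% with only the groups compared, 61.3% with array weights and 62.1% with array weights by sex.

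In females array weights gave 421, 2587 and 1165, array weights by sex 469, 2346 and 1234, only the groups compared 120, 1697 and 338, and only female arrays 177, 1595 and 539. One probe set per gene gave 44, 190 and 36, adjustment over all comparisons 190, 609 and 304, and unadjusted p with a 1.5-fold limit 429, 1218 and 728. Quantile normalization gave 177 on soy formula against sow milk and 28 on soy against milk formula. With 1 array left out the counts were 42 to 81, 142 to 378 and 8 to 66, and the moves of over 1.5 times came from arrays of females. On milk formula against sow milk the counts were 44 and 42 without sow-fed replicates 2 and 3, and 48 and 43 without milk formula replicates 2 and 3. The counts on soy formula against sow milk were 165, 181 and 142 without the sow-fed replicates, and 210, 158 and 165 without the soy formula replicates. On soy against milk formula they were 36, 37 and 38 without the sow-fed replicates, 22 and 8 without milk formula replicates 1 and 2, and 11 and 29 without soy formula replicates 2 and 3. After quantile normalization 42.9% of the calls on soy against milk formula were higher, from 65.5%, and on milk formula against sow milk array weights gave 41.1%, array weights by sex 42.2%, only female arrays 45.8%, adjustment over all comparisons 49.5% and unadjusted p with a 1.5-fold limit 48.3%, from 62.3%. On soy formula against sow milk unadjusted p with a 1.5-fold limit gave 49.0%, from 58.2%.

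For male against female over all diets a 1.5-fold limit gave 7688, unadjusted p with that limit 7690 and 1 probe set per gene 4832. Among sow-fed piglets 1 probe set per gene gave 3456 and quantile normalization 4755, of which 47.9% were higher in males, from 23.9%. Over all diets 41.2% of the calls were higher in males, which became 22.5% without dim probe sets, 17.2% with a 1.5-fold limit and 49.9% after quantile normalization. With all arrays the groups compared are the whole design, so that alternative has no separate value over all diets. Fits without 1 array gave 14036 to 14989 and 6679 to 9231.

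The interaction counts (1, 3 and 0) were the least stable. Both kinds of array weights gave 0 on milk and 0 on soy formula against sow milk, and only the groups compared 0 on milk formula. On soy formula against sow milk trended variances gave 6, quantile normalization 8, no dim probe sets 5, 1 probe set per gene 5 and the replicate block 1. Quantile normalization gave 2 on soy against milk formula. Adjustment over all comparisons gave 133, 230 and 198, and unadjusted p with a 1.5-fold limit 1090, 1519 and 1468. Leaving out 1 array gave 0 to 3, 0 to 27 and 0 to 3. On milk formula 9 arrays gave 0 when left out: male sow-fed replicates 1 and 3, male milk formula replicates 1, 2 and 3, female sow-fed replicates 1 and 2, and female milk formula replicates 2 and 3. The count was 2 without male sow-fed replicate 2, male soy formula replicate 3 or female sow-fed replicate 3, and 3 without male soy formula replicate 2. On soy formula against sow milk it was 27, 5 and 8 without male soy formula replicates 1, 2 and 3, 8 and 0 without male sow-fed replicates 1 and 2, 1 and 7 without female sow-fed replicates 1 and 2, and 0 without female soy formula replicate 2. On soy against milk formula it was 1 without male milk formula replicate 3 and 3 without male soy formula replicate 3. Of the calls on soy formula against sow milk 12.5% were higher after quantile normalization, from 0. Adjustment over all comparisons gave 40.9% there and unadjusted p with a 1.5-fold limit 43.4%. On milk formula against sow milk these 2 gave 58.6% and 60.6%, from 0.

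An estimated correlation between genes lowered the lists past the camera test from 15 to 3 on milk formula against sow milk, from 17 to 3 on soy formula against sow milk, from 17 to 1 on soy against milk formula and from 14 to 0 between the sexes. Between the sexes quantile normalization also gave 0 lists, and 2 remained without dim probe sets. For the 3 diet comparisons the other alternatives gave 14 to 18 lists, and leaving out 1 array 11 to 17, 14 to 18 and 14 to 18. Between the sexes leaving out 1 array gave 12 to 15. No list past the test changed direction in any alternative tried for lists.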

Other observations

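No test in this part was chosen in order to explain a result, and the lists were written before the data were examined. Some genes outside the main comparisons' themes changed too. HNF4A, a master regulator of hepatocyte genes, rose by 0.96 (SE 0.16) on milk formula and by 1.20 (SE 0.16) on soy formula. The imprinted gene PEG10 fell by 2.11 (SE 0.38) and 2.55 (SE 0.38), and the caveolae gene CAV1 by 1.32 (SE 0.29) and 1.66 (SE 0.29). On milk formula CAV1 had adjusted p = 0.0426, up to 0.149 over the alternatives, in 16 of which it was not past the threshold. AGT, the angiotensin precursor, fell by 0.89 (SE 0.12) on milk formula and by 1.35 (SE 0.12) on soy formula, where F12 (-0.57, SE 0.11) was the other called of 12 oestrogen-responsive genes. On soy formula that list had a median of -0.08 (3 fell adjusted over the list alone, adjusted p = 0.035, and adjusted p = 0.139 with an estimated correlation) and 0 genes higher.

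The metallothionein MT1A rose by 1.08 (SE 0.19) on milk formula and fell by 0.72 (SE 0.19) on soy formula, each against sow milk, the latter with adjusted p = 0.0434 and up to 0.123 over the alternatives. In the growth hormone and insulin axis 0 of 12 genes were called on either formula, with IGF1 at 0.13 (SE 0.21) and 0.06 (SE 0.21) and IGFBP1 at -2.01 (SE 0.61, adjusted p = 0.178) and -1.65 (SE 0.61, adjusted p = 0.182). The clock, cell cycle, ribosomal protein and lipoprotein lists held 0 or 1 called gene per direction in every diet comparison. Their medians on soy formula against sow milk were -0.15, -0.07, 0.12 and -0.08. On milk formula against sow milk the ribosomal protein list passed the camera test, but it lost its call with an estimated correlation.

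Of 9 endothelial markers 2 fell on soy formula against sow milk, CDH5 by 0.91 (SE 0.15) and TEK by 0.71 (SE 0.16), with 0 higher and 7 not called (5 fell adjusted over the list alone, median -0.47, adjusted p = 9.85e-06, and adjusted p = 0.0937 with an estimated correlation). Of 12 T and NK cell markers 0 were called (median 0.02, mean -0.03), and 11 of these 12 were dim, with a median ratio of 0.5 or less. Of 18 interferon-stimulated genes 0 were called either, but the list shifted down (median -0.29, adjusted p = 0.00784, and adjusted p = 0.453 with an estimated correlation). Of 12 hepatocyte markers HNF4A was higher, PCK1 and SERPINA1 lower and 9 not called (median -0.18, adjusted p = 0.035, and adjusted p = 0.39 with an estimated correlation). SERPINA1 was not past the threshold in 16 alternatives (adjusted p up to 0.138), nor TEK in 5 (0.0819). For iron handling on milk formula the median was 0.09 and the mean 0.47, with HAMP at 4.96, ID1 at 2.31 and TFRC at -2.47. On soy formula against sow milk the median of the stellate markers was 0.06, the mean -0.04 and the test direction up, with 1 of 6 called (RGS5, -0.79).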
